A study of Mus musculus with 19 samples.

How the data were processed

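Gene expression was measured with Affymetrix arrays in the sciatic nerve of DBA/2J mice, an inbred strain, in 4 groups that crossed diabetes with rosiglitazone treatment. Streptozotocin, which destroys insulin-producing cells, was used to make mice diabetic, and rosiglitazone is an agonist of the nuclear receptor PPAR gamma. Per the labels' protocols, total RNA was extracted with RNeasy Mini columns, and was amplified and biotin-labelled with the NuGEN Ovation system. The series design text gives 5 mice per group, 1 array each, and says that 1 control array was left out by the authors after quality control. The groups therefore held 4 control vehicle arrays, 5 diabetic vehicle arrays, 5 control rosiglitazone arrays and 5 diabetic rosiglitazone arrays, 19 in all. Groups and replicate numbers were taken from the sample titles, and no replicate number is shared between groups.

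The deposited values are 1 intensity per probe set and array on a linear scale, and the submitters' processing notes name RMA without a version. RMA combines background correction, quantile normalization and median polish of the probes of a probe set. It returns log2 values, and the step that put them on a linear scale is not given in the sources used here, nor are the software and its settings. Intensities ran from 3.76 to 30602, and the arrays' medians from 83.3 to 101.7, so the arrays were not fully equal in distribution. Scanner files were not used here. The table held 45101 probe sets, of which 64 were control probe sets and were left out of the tests. Of the other 45037, 34945 had 1 gene symbol in the platform annotation, 932 had several and 9160 had none listed. The gene identifiers of 34741 probe sets were found in the reference gene table, and 0 symbols changed. Probe sets with several symbols or none were not named.

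Values were put on the log2 scale with no offset. Each of the 18193 genes with a symbol was represented by its probe set with the highest mean over the 19 arrays, and genes whose mean lay above the 40th percentile of all probe sets that are not controls, a log2 intensity of 5.54, were tested. This left 13460 genes. A linear model with a mean for each of the 4 groups was fitted with limma 3.58.1 in R 4.3.3, with moderated variances (eBayes) and Benjamini-Hochberg adjustment within each comparison at 0.05. Differences are log2 changes with the standard error (SE) of the model. 5 comparisons were made, namely diabetes under vehicle, rosiglitazone in diabetic mice, rosiglitazone in control mice, diabetes under rosiglitazone, and the interaction, which is the difference between both rosiglitazone effects. The design names mice as the unit, so limma p-values measure the spread between arrays of different animals. That spread also holds differences in tissue content and RNA integrity between samples. The number of arrays limits the precision.

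Gene lists for pathways and cell types that could be present in a nerve sample were fixed before the data were examined, as were the groups, the tests, the rule for naming genes and most of the other settings tried. Of 36 planned lists, 35 had the minimum of 5 tested genes. The remaining list, of red blood cell genes, had 4. Each list was tested with camera from limma at a preset correlation of 0.01 between genes, again with the correlation estimated from the residuals, and with fry, with adjustment over the 35 lists of a comparison. Camera compares a list with all other genes, while fry tests whether a list's genes move one way on balance. At the preset correlation, camera p-values rest mainly on the spread across genes rather than on that between animals. For each list the number of genes past the threshold when adjusted over the list alone is given. 4 further lists, of sensory neuron cell body, oligodendrocyte, astrocyte and further ganglion genes, were made after the data were seen and entered no camera test. Per array, the mean of each list's genes after centring every gene on its mean over the 19 arrays was taken as the list's level, and groups were compared with two-sided exact permutation tests of the difference of means over all 126 or 252 splits. RNA integrity was read from the 3' minus 5' log2 difference of the Gapdh and beta-actin control probe sets and tested the same way.

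Genes were named by a fixed rule. In the first 3 comparisons the 8 genes with the highest and the 8 with the lowest change past the threshold were to be named, or the 5 with the smallest p where fewer than 5 passed, together with up to 4 members with the smallest p of each list past the threshold, and 19 genes of lipid metabolism, myelin, oxidative stress and steroid or clock response in every case, of which 15 were tested. In the other 2 comparisons the 3 genes with the smallest p were named where none passed. All genes of the rule are in the tables, and all those named in every case are in the text. Of the members of each list the text gives some or none, a choice made after their values were seen. Genes named outside the rule are said to be so.

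The model was tested on simulated data with the spread of the real genes, for diabetes under vehicle and all 13460 genes. Of 50 genes changed by each size, 16%, 56%, 92% and 94% were recovered at log2 changes of 0.5, 1, 2 and 3, with 8 false calls. A simulated shift of 0.4 in the oxidative phosphorylation list was called, with 0 of the other lists. The simulated genes were drawn independently of each other. These counts therefore do not show how often genes or lists are falsely called when genes move together. Correlations between effects were described across genes, which are not independent replicates, and were set against 100 relabelings of the arrays. For every count, 100 of the 126 splits of the arrays of a comparison (100 relabelings for the interaction) were used. The real grouping was 1 of them, and the others were drawn with a fixed seed.

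Other settings fixed before the data were examined were no filter, a filter at the 60th percentile (10632 genes), the mean of a gene's probe sets, 27022 probe sets tested singly, quantile normalization, median centring, eBayes with trend and robust variances, array weights, a fit of the compared groups alone, adipocyte and skeletal muscle levels as covariates, the Gapdh 3' minus 5' difference as covariate, a threshold of 0.10, and leaving out each array in turn. Chosen after seeing the data were the sensory neuron level as covariate, that level with the adipocyte and muscle levels, and fits without 5 arrays low in sensory neuron transcripts or without the 2 arrays with the highest 3' minus 5' differences. Tables were handled with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.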

Results

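Transcripts of sciatic nerve were profiled in 19 DBA/2J mice, 4 control mice given vehicle, 5 diabetic mice given vehicle, 5 control mice given rosiglitazone and 5 diabetic mice given rosiglitazone. Arrays are named by group, CV and DV for control and diabetic vehicle and CR and DR for control and diabetic rosiglitazone, with the number in their titles. The study asked whether rosiglitazone, an agonist of PPAR gamma used against insulin resistance, alters neuropathy in a streptozotocin model of diabetes. The median intensity per array ran from 83.3 to 101.7. The level of the 22 myelin genes ran from -1.03 in array CR715 to 0.38 in array CV702. Mbp, which encodes myelin basic protein, was between 13.83 and 14.44 on the log2 scale, and Pmp22, a myelin membrane protein, between 13.82 and 14.34.

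The samples differed in transcripts of several tissues, shown here by genes that, besides Adipoq, were chosen after their values were seen. Transcripts of sensory neuron cell bodies, which lie in ganglia rather than in the nerve trunk, spanned a wide range across arrays. Isl1, a transcription factor of sensory neurons, ran from 3.83 to 11.35, Scn10a, a sodium channel of pain-sensing neurons, from 3.82 to 10.10, and Calcb, a sensory neuropeptide gene, from 3.70 to 12.30. The mean of the 14 measured sensory neuron cell body markers, a list made after the data were seen, was -2.91, -3.17 and -3.32 in arrays DV706, DV707 and DV709, -3.07 in array CR715 and -3.15 in array DR716. On the other 14 arrays it lay between 0.02 and 1.98. Fat and muscle genes varied as widely, with Adipoq, the adipocyte hormone adiponectin, between 5.48 and 13.80 and Acta1, skeletal muscle actin, between 4.67 and 13.27. The 3' minus 5' difference of the Gapdh control probe sets, which grows as RNA breaks down, was 3.71 and 4.38 in arrays DV706 and DV707 and 1.75 in array DR716, against 1.00 to 1.37 on the rest. None of these levels passed the adjusted threshold between groups by exact permutation test. With only 126 or 252 splits, a single difference could not pass it on its own, however large. The tests therefore cannot show that the groups were alike. The mean sensory neuron level was -1.25 in diabetic and 0.69 in control vehicle mice (exact permutation p = 0.175, adjusted p = 0.921 over 16 tests of lists made after the data were seen). The mean Gapdh difference was 2.31 in diabetic and 1.23 in control vehicle mice. The smallest two-sided exact p over 28 tests of marker levels was 0.0238 (adjusted p = 0.667), for brown fat and thermogenic markers in control mice with and without rosiglitazone, and over 8 tests of RNA integrity it was 0.0714 (adjusted p = 0.444), for beta-actin in diabetic and control vehicle mice.

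**Figure D1:**
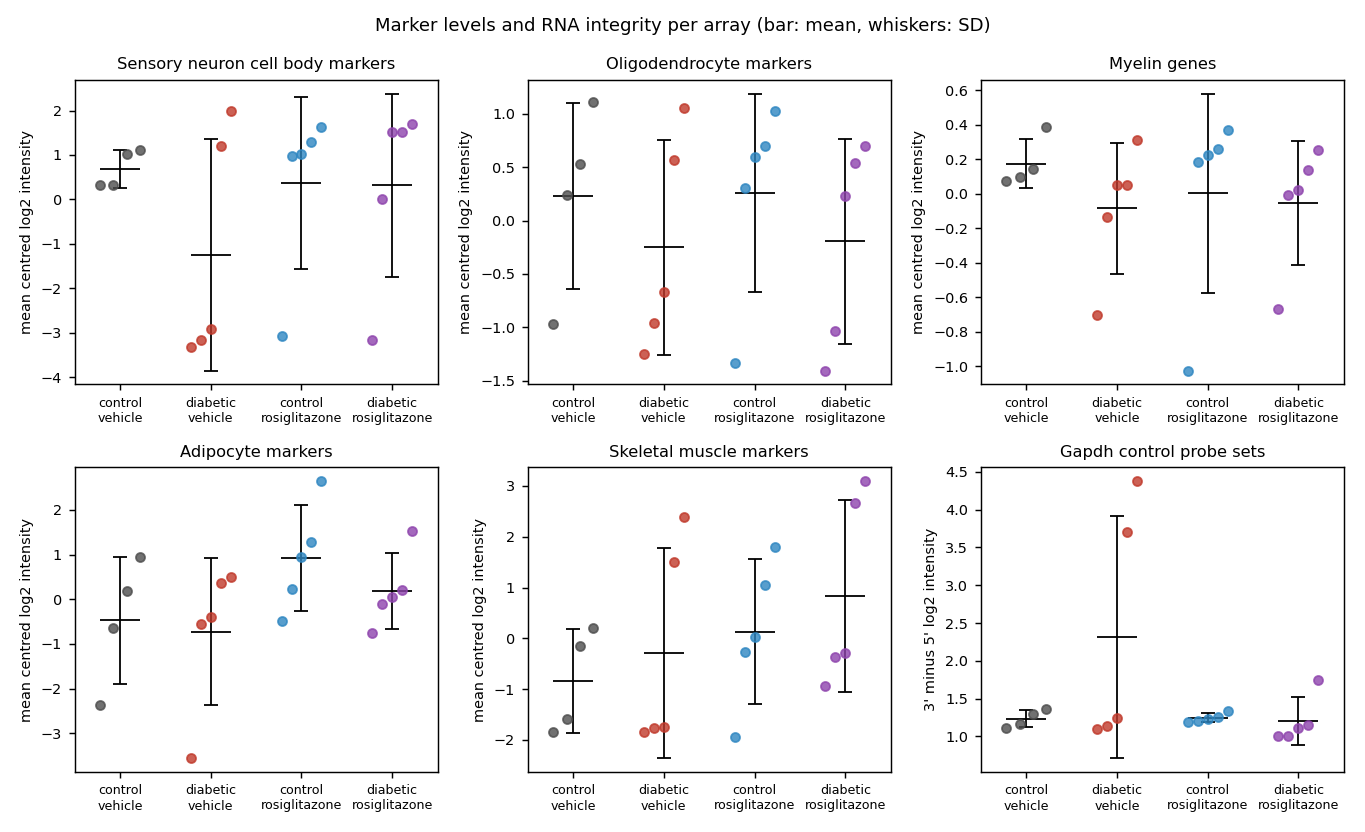
Mean centred log2 intensity of 5 marker lists and the 3' minus 5' log2 difference of the Gapdh control probe sets, 1 point per array in each of the 4 groups, with the group mean as a bar and the SD as whiskers. The sensory neuron level was between -3.32 and -2.91 on 5 arrays and between 0.02 and 1.98 on the other 14, and the Gapdh difference reached 4.38 in the diabetic vehicle group.

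The first comparison asked what diabetes does to the nerve in mice given vehicle. Endothelial genes lay higher in diabetic nerve, in 16 of 18 members with a median log2 change of 0.63. Vwf, which encodes von Willebrand factor, was at 12.02 ± 0.90 (SD, n = 5) in diabetic and 10.41 ± 0.36 (SD, n = 4) in control mice. Robo4, a vascular guidance receptor, differed by 1.60 (SE 0.40), and Erg, an endothelial transcription factor, by 1.63 (SE 0.44). Heat shock and unfolded protein response genes, which encode chaperones, folding enzymes and regulators of the stress response, lay lower in 23 of 28 members with a median of -0.17. Hsp90b1, the chaperone GRP94, was at 11.49 ± 0.44 (SD, n = 5) against 12.35 ± 0.13 (SD, n = 4), and Sdf2l1 and Pdia3, further members, differed by -1.62 (SE 0.48) and -1.11 (SE 0.35). Pdia3 was at 10.15 and 10.48 in arrays DV706 and DV707, the arrays with the highest Gapdh 3' minus 5' differences, and between 11.60 and 12.29 in the other 3 diabetic vehicle arrays. Without arrays DV706 and DV707 the differences were -0.56 for Hsp90b1 and -0.48 for Pdia3, and 0.96, 0.99 and 0.90 for Vwf, Robo4 and Erg. The median of the chaperone list stayed at -0.17 without them. No single gene passed the threshold.

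Both lists passed camera at the preset correlation. The adjusted p was 2.10e-04 for the endothelial list, with 4 genes past the threshold when adjusted over the list alone (adjusted p = 0.734 with an estimated correlation). For heat shock and unfolded protein response genes it was 4.34e-04, with 7 genes past the threshold when adjusted over the list alone (adjusted p = 0.734 with an estimated correlation). Pdia4, a protein disulfide isomerase, had the largest difference of the named members of that list, -2.29 (SE 0.55), though only 1 of its 2 probe sets had that sign. The median of the heat shock and unfolded protein response list was -0.28 without array CV704 and -0.11 without array CV705. The endothelial level was 1.06 and 0.71 in arrays DV706 and DV707, the arrays with the highest Gapdh 3' minus 5' differences, and between -0.36 and 0.31 in the other 3 diabetic vehicle arrays. Without arrays DV706 and DV707 the endothelial median was 0.37. It was 0.19 without the 5 arrays low in sensory neuron transcripts, where the call ended.

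Interferon response genes lay higher in 25 of 29 members, with a median of 0.27 (adjusted p = 0.00149, 2 genes past the threshold when adjusted over the list alone, and adjusted p = 0.927 with an estimated correlation). Tap1, a peptide transporter for antigen presentation, differed by 0.65 (SE 0.19), Oasl1 by 1.42 (SE 0.42) and Rsad2, the antiviral protein viperin, by 0.75 (SE 0.25). Without arrays DV706 and DV707 the interferon median was 0.15 and no longer past the threshold, and Tap1 differed by 0.32. Circadian clock genes lay higher in 14 of 18 members, with a median of 0.39 (adjusted p = 0.00969, 2 genes past the threshold when adjusted over the list alone, and adjusted p = 0.734 with an estimated correlation). The clock repressor Cry2 was at 10.28 ± 0.14 (SD, n = 5) against 9.57 ± 0.22 (SD, n = 4) with no overlap between groups, and Per2, a further repressor of the clock, and Dbp, a clock output gene, differed by 1.29 (SE 0.38) and 1.27 (SE 0.47). The clock call ended without array CV702 (median 0.31, and a difference of 0.85 for Per2) and without array DV709 (median 0.28). Fkbp5, a gene induced by glucocorticoids, differed by 1.02 (SE 0.32).

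Extracellular matrix genes lay lower in 32 of 45 members, with a median of -0.15 (adjusted p = 0.00149, 7 genes past the threshold when adjusted over the list alone, and adjusted p = 0.734 with an estimated correlation). The collagens Col3a1 and Col1a1 differed by -0.40 (SE 0.10) and -0.36 (SE 0.10), and Serpinh1, a collagen chaperone, by -0.93 (SE 0.26). Fibroblast markers, which share members with the matrix list, lay lower in 15 of 17 members, with a median of -0.19 (adjusted p = 0.00555, 3 genes past the threshold when adjusted over the list alone, and adjusted p = 0.734 with an estimated correlation). Without array DV708 both calls ended, with medians of -0.03 for the matrix and -0.17 for fibroblasts, and the fibroblast median was -0.09 without array CV705. The matrix median was -0.24 without arrays DV706 and DV707.

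Cholesterol synthesis genes lay lower in 17 of 20 members, with a median of -0.27 (adjusted p = 0.00969, 0 genes past the threshold when adjusted over the list alone by limma with 5 at an unadjusted p under 0.05, and adjusted p = 0.973 with an estimated correlation). Sc5d and Cyp51, enzymes of the pathway, differed by -0.64 (SE 0.20) and -0.60 (SE 0.28). The call ended without array DV707 (median -0.14), and without arrays DV706 and DV707 the median was -0.004 and Cyp51 differed by -0.34. Neuron and axon markers lay lower in 18 of 19 members, with a median of -1.52 (adjusted p = 0.00249, and adjusted p = 0.973 with an estimated correlation), but their levels followed the sensory neuron content of the samples, with -2.13, -2.92 and -2.57 in arrays DV706, DV707 and DV709 and 1.73 and 1.06 in arrays DV708 and DV710. That median was -0.95 without array DV707 and -1.07 without array DV709, where the call ended. It was 0.76 without the 5 arrays low in sensory neuron transcripts. Isl1, Pou4f1, Scn10a, Trpv1 and Tac1 are in this list and also among the sensory neuron markers that set those arrays apart. The match of the levels and the shift without those arrays therefore follow in part from shared genes. Antioxidant genes lay lower in 26 of 41 members, with a median of -0.12 (adjusted p = 0.0418, 1 gene past the threshold when adjusted over the list alone, and adjusted p = 0.734 with an estimated correlation). Gpx7, an endoplasmic reticulum peroxidase, differed by -0.53 (SE 0.13), and the antioxidant call ended without any 1 of arrays CV705, DV706, DV708 and DV709, with medians of -0.11, -0.13, -0.13 and -0.15, and the median was -0.20 without array CV702 or DV710.

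With limma, 0 of 13460 genes passed an adjusted p of 0.05 in this comparison, and 2439 (18.1%, where chance gives 5%) had an unadjusted p under 0.05, 1444 of them higher and 995 lower in diabetic mice. The smallest adjusted p was 0.238. Genes as far down as Dbp, with an unadjusted limma p of 0.0146, shared it, so it does not single out the 5 genes with the smallest p. Besides Cry2, these were Ccl7, a chemokine for monocytes, at 8.82 ± 0.62 (SD, n = 5) against 10.29 ± 0.19 (SD, n = 4), Lum, the matrix proteoglycan lumican, at 11.70 ± 0.43 against 12.52 ± 0.04, Gm17586 at 7.97 ± 0.08 against 7.04 ± 0.36, and Pole4, a DNA polymerase subunit, at 10.34 ± 0.21 against 10.98 ± 0.08. Only 1 of the 3 probe sets of Pole4 had that sign. The number at an unadjusted p under 0.05 was 606 without arrays DV706 and DV707, 764 with the Gapdh difference as covariate and 3932 without array DV710. It was 1223, 1388 and 1490 without arrays DV706, DV707 and CV705, 1537 with array weights and 1539 without the 5 arrays low in sensory neuron transcripts. Myelin genes as a list were not past the threshold (adjusted p = 0.0961, 15 of 22 lower).

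The 15 genes to be named in every case did not pass the threshold, and the ranges given for them are those over single arrays left out. Of genes of fat and lipid use, Pparg, the receptor of the drug, differed by 0.74 (SE 0.89, from 0.25 without DV707 to 1.10 without CV705), Adipoq by -0.30 (SE 1.24, from -1.36 without CV702 to 1.05 without DV709), Fabp4, the adipocyte fatty acid carrier, by -0.20 (SE 0.72, from -0.86 without CV702 to 0.62 without DV709) and Cd36, a fatty acid transporter, by -0.34 (SE 0.67, from -0.70 without CV702 to 0.08 without DV709). The differences of Pdk4, a kinase that holds back glucose oxidation, and Angptl4, a lipase inhibitor, were 0.36 (SE 0.18) and 0.49 (SE 0.42, from 0.28 without CV702 to 0.66 without CV705). Of the oxidative stress genes, Hmox1, heme oxygenase, differed by -0.69 (SE 0.56, from -0.92 without DV710 to -0.44 without DV708), Txnip, a thioredoxin inhibitor, by -0.28 (SE 0.18, from -0.39 without DV710 to -0.18 without DV708), Sod2, mitochondrial superoxide dismutase, by -0.49 (SE 0.18) and Cat, catalase, by 0.09 (SE 0.11, from 0.05 without DV707 to 0.16 without DV708). Ngfr, a neurotrophin receptor, differed by -0.35 (SE 0.57, from -0.70 without DV708 to -0.06 without DV707), Pmp22 by 0.01 (SE 0.09, from -0.04 without DV706 to 0.03 without DV707) and Mbp by 0.04 (SE 0.10, from -0.004 without DV706 to 0.08 without CV702). Dbp and Fkbp5 are given above. With arrays DV706 and DV707 left out, the differences were 0.02 for Pparg, -1.22 for Adipoq, -0.78 for Fabp4, -0.84 for Cd36, 0.15 for Pdk4, 0.27 for Angptl4, 0.15 for Ngfr and -0.02 for Cat. The probe sets of a gene disagreed in sign for Fabp4 (2 of 4 with the sign given), Cd36 (2 of 3), Mbp (5 of 8), Sod2 (2 of 4) and Cat (1 of 2).

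**Figure D2:**
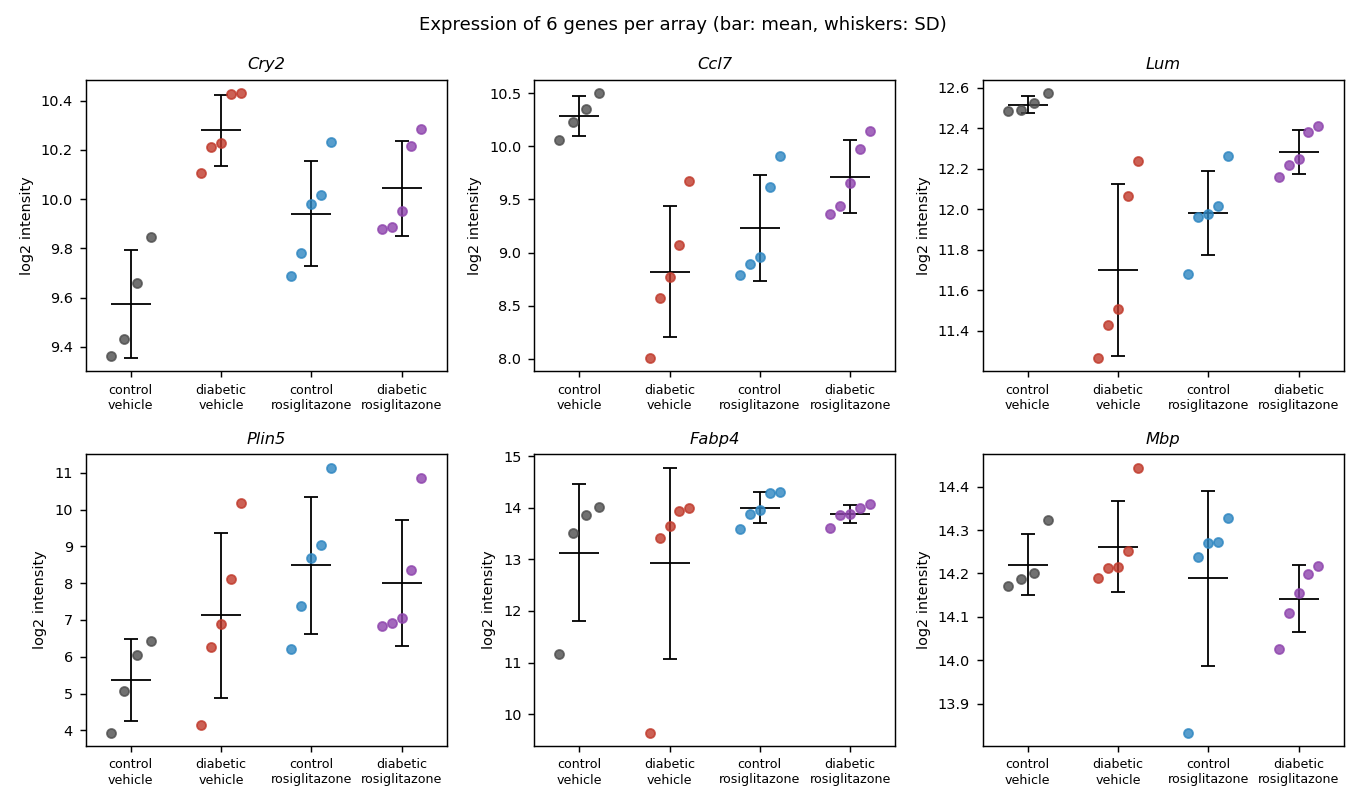
Log2 intensity of 6 genes, 1 point per array in each of the 4 groups, with the group mean as a bar and the SD as whiskers. Ccl7 was at 10.29 in control vehicle mice and 8.82 in diabetic vehicle mice, Cry2 at 9.57 and 10.28, and Mbp at 14.22 and 14.26.

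The second comparison asked what rosiglitazone does in diabetic mice. Genes of oxidative phosphorylation lay higher with the drug in 41 of 60 members, with a median of 0.11, and the complex I subunits Ndufa7 and Ndufa8 differed by 0.22 (SE 0.08) and 0.37 (SE 0.14). Antioxidant genes lay higher in 28 of 41, with a median of 0.16. Gpx7 was at 11.59 ± 0.07 (SD, n = 5) with the drug and 11.14 ± 0.27 (SD, n = 5) without, and Txn2, mitochondrial thioredoxin, differed by 0.45 (SE 0.15). Endothelial genes lay lower in 17 of 18, with a median of -0.27, among them Erg by -1.16 (SE 0.41) and Robo4 by -0.97 (SE 0.38). When arrays DV706 and DV707 were left out, Ndufa8 differed by 0.21, Gpx7 by 0.28, Txn2 by 0.20, Erg by -0.43 and Robo4 by -0.36. No single gene passed the threshold.

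These 3 lists passed camera, with adjusted p of 1.09e-04 for oxidative phosphorylation, 0.00545 for antioxidant genes and 0.00545 for endothelial markers (adjusted p = 0.889 with an estimated correlation for each). In all 3, limma put 0 genes past the threshold when adjusted over the list alone, with 14, 5 and 2 at an unadjusted p under 0.05. The oxidative phosphorylation median was 0.07 without array DV707, and 0.03 and not past the threshold without arrays DV706 and DV707. The antioxidant median was 0.09 without array DV709 or DR719 and 0.27 without array DV710. The endothelial call ended without array DR716 (median -0.28), and its median was -0.13, -0.51, -0.15 and -0.41 without arrays DV706, DV708, DR717 and DR719. The endothelial level was 1.06 and 0.71 in arrays DV706 and DV707. It lay between -0.36 and 0.31 in the other diabetic vehicle arrays and between -0.56 and 0.42 in diabetic mice given the drug.

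Adipocyte markers lay higher in 14 of 14 members, with a median of 0.80 (adjusted p = 0.00545, and adjusted p = 0.889 with an estimated correlation). Cidec, a lipid droplet protein, was at 11.23 ± 0.88 (SD, n = 5) against 9.02 ± 2.70 (SD, n = 5), and Fabp4, the adipocyte fatty acid carrier, at 13.88 ± 0.18 against 12.93 ± 1.85. Array DV709 held Fabp4 at 9.64. Without it Cidec differed by 1.06 and Fabp4 by 0.13, and the adipocyte median was 0.19 and the call ended, as it did without array DR716 (median 0.51). Skeletal muscle markers lay higher in 28 of 28 members, with a median of 0.85 (adjusted p = 0.00258, and adjusted p = 0.889 with an estimated correlation). That call ended without arrays DV709, DV710, DR716 or DR720 (medians 0.57, 0.47, 0.48 and 0.40), and the median was 1.49 without array DV706 and 0.47 without array DV707. Neuron and axon markers lay higher in 19 of 19, with a median of 1.04 (adjusted p = 0.00455, and adjusted p = 0.889 with an estimated correlation). Without arrays DV707 or DV709 the neuron median was 0.47 and 0.73 and the call ended, without arrays DV708 or DR716 it was 1.66 and 1.70, and it was -0.30 without the 5 arrays low in sensory neuron transcripts. That last value leaves out arrays chosen by markers that share genes with this list. PPAR gamma target genes were higher in 21 of 26 members, with a median of 0.41, and did not pass the threshold (adjusted p = 0.0511).

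Fibroblast markers lay higher in 13 of 17 members, with a median of 0.16 (adjusted p = 0.0113, 1 gene past the threshold when adjusted over the list alone, and adjusted p = 0.889 with an estimated correlation). Lum was at 12.28 ± 0.11 (SD, n = 5) with the drug and 11.70 ± 0.43 (SD, n = 5) without. Macrophage markers lay higher in 16 of 21, with a median of 0.20 (adjusted p = 0.0114, and adjusted p = 0.889 with an estimated correlation), with the complement gene C1qa differing by 1.19 (SE 0.42). The level of C1qa was 8.64 and 8.92 in arrays DV706 and DV707, the arrays with the highest Gapdh 3' minus 5' differences, and between 10.22 and 11.60 in the other 3 diabetic vehicle arrays. With these arrays left out, C1qa and Lum each differed by 0.35. The fibroblast call ended without arrays DV708, DV709 or DR716 (medians 0.13, 0.15 and 0.14). The macrophage call ended without arrays DV708, DV709, DR716 or DR719 (medians 0.18, -0.02, 0.14 and 0.13), and its median was 0.38 and 0.32 without arrays DV707 and DV710. With limma, 0 of 13460 genes passed an adjusted p of 0.05, and 1305 (9.70%) had an unadjusted p under 0.05, 556 higher and 749 lower with the drug. The smallest adjusted p was 0.497. The 5 genes with the smallest p were Ccdc114, a ciliary protein, with a difference of -0.74 (SE 0.15), Becn1, a regulator of autophagy, at 11.61 ± 0.05 against 11.98 ± 0.14, Myo1h with -0.37 (SE 0.08), Aqp11, a water channel, at 6.16 ± 0.32 against 7.16 ± 0.55, and Mier2 with -0.48 (SE 0.11). The number at an unadjusted p under 0.05 was 258 without arrays DV706 and DV707 and 341 with the Gapdh difference as covariate. It was 439 with only the compared groups, 569 without the 5 arrays low in sensory neuron transcripts, 867 with the sensory neuron level as covariate and 2654 with adipocyte and muscle levels as covariates. It was 447, 618 and 769 without arrays DV706, DV707 and DR717, and 2999, 2686 and 2175 without arrays DV710, DR716 and DV708. Without arrays DR718 and DR719 it was 793 and 807.

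The 15 genes to be named in every case did not pass here either. Of genes of fat and lipid use, Pparg differed by -0.16 (SE 0.84, from -0.78 without DR716 to 0.33 without DV707), Adipoq by 1.52 (SE 1.17, from 0.16 without DV709 to 2.00 without DV707), Fabp4 by 0.96 (SE 0.68, from 0.13 without DV709 to 1.22 without DV710) and Cd36 by 0.62 (SE 0.63, from 0.21 without DV709 to 0.93 without DV707). The differences of Pdk4 and Angptl4 were -0.30 (SE 0.17) and -0.59 (SE 0.40). Of the oxidative stress genes, Hmox1 differed by 0.03 (SE 0.53, from -0.29 without DR719 to 0.58 without DR720), Txnip by 0.16 (SE 0.17, from 0.06 without DV708 to 0.28 without DV710), Sod2 by 0.21 (SE 0.17, from 0.13 without DR718 to 0.32 without DR720) and Cat by -0.15 (SE 0.10). Pparg also turned positive without array DR718 (0.16) and was at -0.52 without array DV709, and Cd36 was at 0.37 without array DR716. Ngfr differed by 0.39 (SE 0.54, from 0.11 without DV707 to 0.74 without DV708), Dbp by -0.16 (SE 0.44, from -0.35 without DR716 to -0.04 without DR718), Fkbp5 by -0.31 (SE 0.30, from -0.49 without DV706 to -0.17 without DV709), Pmp22 by -0.08 (SE 0.09, from -0.10 without DV707 to -0.03 without DV706) and Mbp by -0.12 (SE 0.09, from -0.14 without DR719 to -0.08 without DV706). With arrays DV706 and DV707 left out, the differences were 0.56 for Pparg, 2.44 for Adipoq, 1.53 for Fabp4, 1.12 for Cd36, -0.09 for Pdk4, -0.37 for Angptl4, 0.07 for Sod2, -0.04 for Cat, -0.11 for Ngfr, -0.06 for Dbp and -0.08 for Mbp. The probe sets disagreed in sign for Ngfr (2 of 3 with the sign given), Dbp (1 of 2) and Mbp (6 of 8).

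**Figure D3:**
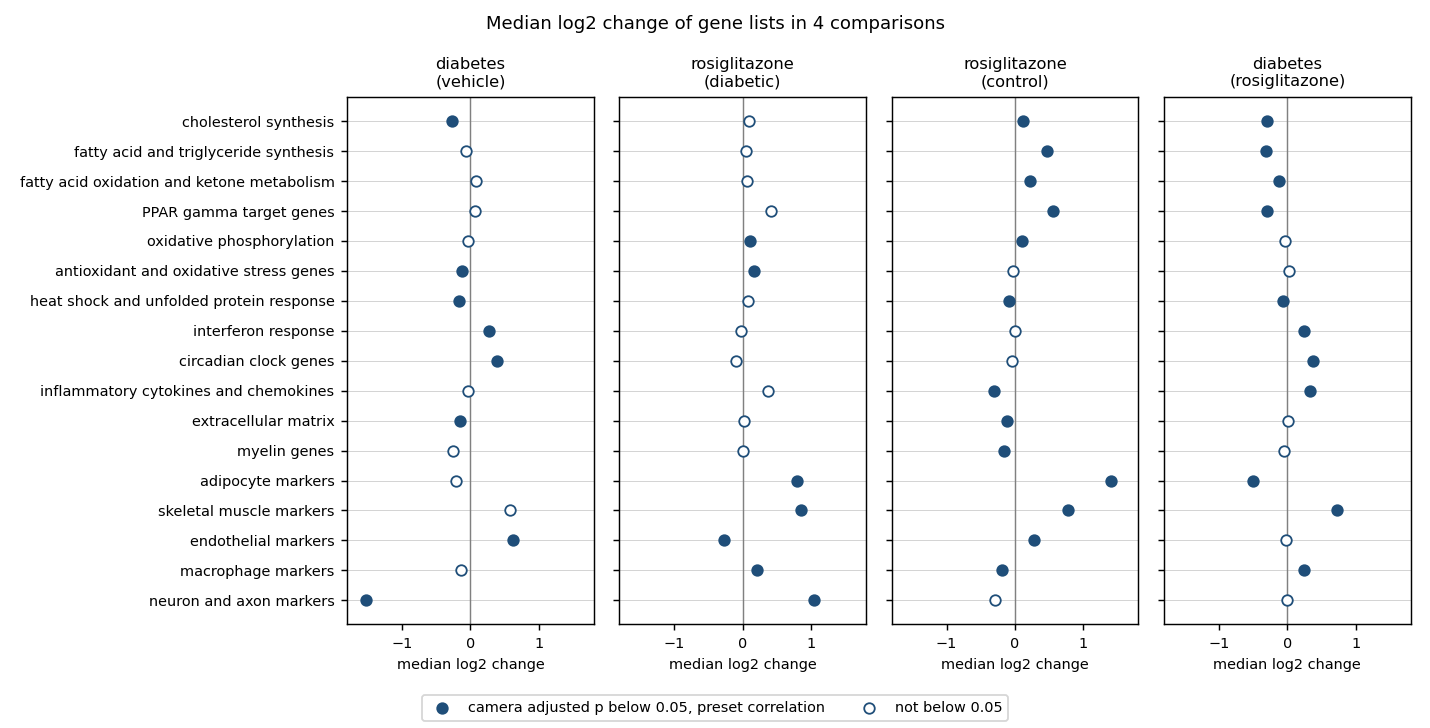
Median log2 change of 17 gene lists in the 4 comparisons between pairs of groups. Filled points had a camera adjusted p under 0.05 at the preset correlation, and endothelial markers, for example, lay at 0.63 for diabetes under vehicle and at -0.27 for rosiglitazone in diabetic mice. Both of these comparisons use the diabetic vehicle arrays, so opposite signs can come from that sharing. The same holds for the control rosiglitazone arrays, used for rosiglitazone in control mice and for diabetes under rosiglitazone.

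The third comparison asked what rosiglitazone does in control mice. Target genes of PPAR gamma lay higher with the drug in 25 of 26 members, with a median of 0.56. Plin5, which coats lipid droplets, was at 8.49 ± 1.86 (SD, n = 5) with the drug and 5.37 ± 1.12 (SD, n = 4) without, Plin4, a related protein, at 11.03 ± 1.46 against 8.92 ± 1.65, and Lipe, hormone-sensitive lipase, at 9.66 ± 1.71 against 8.07 ± 0.77. Adipocyte markers lay higher in 14 of 14, with a median of 1.40, and 8 of them are also among the PPAR gamma targets. Genes of fatty acid and triglyceride synthesis were higher in 17 of 21, with a median of 0.47, among them Acaca, acetyl-CoA carboxylase, by 0.65 (SE 0.26). Without array CR715, Acaca differed by 0.41 and Lipe by 0.996, and without array CV702 Plin4 differed by 1.35. No single gene passed the threshold.

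These lists passed camera, with adjusted p of 5.30e-10 for PPAR gamma targets and 2.63e-07 for adipocyte markers (adjusted p = 0.358 with an estimated correlation for both) and 2.05e-06 for fatty acid and triglyceride synthesis (adjusted p = 0.110 with an estimated correlation). In each, limma put 0 genes past the threshold when adjusted over the list alone, with 5, 2 and 4 at an unadjusted p under 0.05. The adipocyte level was 2.64 in array CR715 and -2.37 in array CV702. Without array CV702 the PPAR gamma median was 0.32 and the adipocyte median 0.72, and without array CR715 the PPAR gamma and synthesis medians were 0.32 and 0.25. With adipocyte and muscle levels as covariates the PPAR gamma median was 0.06 and not past the threshold. The adipocyte level is partly built from genes of the PPAR gamma list. This fit therefore cannot tell fat content from a response of those genes.

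Lists of oxidative phosphorylation, fatty acid oxidation, brown fat and muscle genes also lay higher in treated control mice. Oxidative phosphorylation was higher in 53 of 60 members, with a median of 0.10 (adjusted p = 4.48e-08, and adjusted p = 0.358 with an estimated correlation), and Sdhb, a subunit of complex II, differed by 0.35 (SE 0.13). Fatty acid oxidation was higher in 23 of 26, with a median of 0.22 (adjusted p = 4.03e-06, and adjusted p = 0.358 with an estimated correlation), and Acads, an acyl-CoA dehydrogenase, differed by 0.79 (SE 0.27). Without array CR715 the medians of these lists were 0.06 and 0.07, and Sdhb and Acads differed by 0.22 and 0.50. Brown fat and thermogenic markers were higher in 9 of 10, with a median of 0.39 (adjusted p = 0.00172, and adjusted p = 0.0941 with an estimated correlation), among them Cidea at 8.38 ± 1.89 (SD, n = 5) against 6.70 ± 0.54 (SD, n = 4). Their level was 1.44 in array CR715 and between -0.10 and 0.25 in the other 4 treated control mice, against -0.51 to -0.27 in control vehicle mice, and without array CR715 Cidea differed by 0.84. Skeletal muscle markers were higher in 27 of 28, with a median of 0.77 (adjusted p = 6.07e-04, and adjusted p = 0.597 with an estimated correlation), a call that ended without array CR715 (median 0.33), and the median was 0.44, 1.44 and 1.42 without arrays CV703, CV705 and CR712.

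Cytokine, macrophage, neutrophil and matrix lists lay lower in treated control mice, while T and NK cell markers were higher in 5 of 7 members, B and plasma cell markers in 4 of 5 and interferon response genes in 15 of 29, none past the threshold. Chemokines and cytokines were lower in 19 of 26 members, with a median of -0.31 (adjusted p = 0.00331, and adjusted p = 0.476 with an estimated correlation). The monocyte chemokine Ccl2 was at 9.90 ± 0.51 (SD, n = 5) against 10.97 ± 0.17 (SD, n = 4), and Ccl7 at 9.23 ± 0.50 against 10.29 ± 0.19. Macrophage markers were lower in 20 of 21, with a median of -0.19 (adjusted p = 9.67e-04, and adjusted p = 0.594 with an estimated correlation). Neutrophil markers were lower in 7 of 7, with a median of -1.74 (adjusted p = 0.00127, and adjusted p = 0.453 with an estimated correlation), where array CV703 stood at a level of 3.13. Matrix genes were lower in 39 of 45, with a median of -0.11 (adjusted p = 1.86e-05, and adjusted p = 0.358 with an estimated correlation), and Lum differed by -0.54 (SE 0.17). The cytokine call ended without arrays CV705 or CR713 (medians -0.15 and -0.24), and its median was -0.20 and -0.18 without arrays CV702 and CR715. The neutrophil call ended without array CV703 (median -0.53), and the median was -2.88 without array CV704. The matrix median was -0.17 without array CV702 or CR715.

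Myelin genes were lower in 22 of 22 members, with a median of -0.16 (adjusted p = 0.0141, and adjusted p = 0.634 with an estimated correlation), and the call ended without array CV702 (median -0.08) and without array CR715 (median 0.08), whose myelin level was -1.03. In all, 19 lists passed in this comparison, and the other 7 had medians between -0.12 and 0.28. With an estimated correlation 0 lists passed, and with fry 0. With limma, 0 of 13460 genes passed an adjusted p of 0.05, and 381 (2.83%) had an unadjusted p under 0.05, 199 higher and 182 lower, with a smallest adjusted p of 1.00. The 5 genes with the smallest p were C920021L13Rik, with a difference of 0.91 (SE 0.20) and only 1 of 2 probe sets of that sign, Rad51c, a DNA repair gene, with -0.54 (SE 0.13), Stxbp3, a vesicle docking protein, with -0.54 (SE 0.14), Map4k5, a kinase, with -0.65 (SE 0.17), and Ccnt2, a cyclin of transcription elongation, with -0.55 (SE 0.15). With array weights, 20 genes passed, among them Ccl7 at -1.15 (adjusted p = 0.0365 by limma) and Ccl2 at -1.19 (adjusted p = 0.0378 by limma). The number at an unadjusted p under 0.05 was 1198 without the 5 arrays low in sensory neuron transcripts, and 204 and 237 without arrays CV705 and CR711. It was 2074 with array weights, 1117 with sensory neuron, adipocyte and muscle levels as covariates, and 804 with only the compared groups. With the adipocyte and muscle levels, the Gapdh difference or the sensory neuron level as covariates it was 601, 639 and 649.

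The 15 genes to be named in every case did not pass in treated control mice. Of genes of fat and lipid use, Pparg differed by 1.32 (SE 0.89, from 0.66 without CR715 to 1.79 without CR713), Adipoq by 1.43 (SE 1.24, from 0.37 without CV702 to 1.99 without CV705), Fabp4 by 0.87 (SE 0.72, from 0.21 without CV702 to 1.16 without CV705) and Cd36 by 0.55 (SE 0.67, from 0.06 without CR715 to 0.86 without CV705). The differences of Pdk4 and Angptl4 were 0.19 (SE 0.18, from 0.06 without CR715 to 0.26 without CV705) and 0.38 (SE 0.42, from 0.05 without CR715 to 0.75 without CR713). Of the oxidative stress genes, Hmox1 differed by -0.49 (SE 0.56, from -0.63 without CR714 to -0.16 without CR711), Txnip by -0.22 (SE 0.18, from -0.32 without CR715 to -0.10 without CR711), Sod2 by -0.10 (SE 0.18, from -0.22 without CR715 to 0.04 without CR711) and Cat by 0.12 (SE 0.11, from 0.06 without CR715 to 0.17 without CR714). Ngfr differed by -0.10 (SE 0.57, from -0.33 without CR711 to 0.45 without CR715), Dbp by 0.37 (SE 0.47, from 0.01 without CV705 to 0.81 without CV704), Fkbp5 by 0.12 (SE 0.32, from -0.09 without CV702 to 0.31 without CV704), Pmp22 by -0.05 (SE 0.09, from -0.08 without CR713 to 0.02 without CR715) and Mbp by -0.03 (SE 0.10, from -0.07 without CR713 to 0.06 without CR715). The probe sets disagreed in sign for Sod2 (1 of 4 with the sign given), Ngfr (2 of 3) and Mbp (7 of 8).

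The fourth comparison set diabetic against control mice under rosiglitazone. It uses the same control rosiglitazone arrays as the third comparison, with the opposite sign. Lists that moved in opposite directions in both can therefore reflect those shared arrays. Both lists of lipid synthesis genes lay lower in diabetic nerve, with 20 of 20 cholesterol synthesis genes lower by a median of -0.29 (adjusted p = 5.61e-11, and adjusted p = 0.293 with an estimated correlation). Of the fatty acid and triglyceride synthesis genes, 21 of 21 were lower, with a median of -0.31 (adjusted p = 2.16e-09), and the call held with an estimated correlation (adjusted p = 0.0481 with an estimated correlation), as no other did in any comparison, but it was lost with fry (adjusted p = 0.286). Tissue markers moved beside it, with adipocyte markers lower in 13 of 14 members, with a median of -0.50 (adjusted p = 3.21e-04, and adjusted p = 0.469 with an estimated correlation), and skeletal muscle markers higher in 26 of 28, with a median of 0.73 (adjusted p = 7.92e-05, and adjusted p = 0.572 with an estimated correlation). With adipocyte and muscle levels as covariates the median of fatty acid and triglyceride synthesis was -0.29 and past the threshold at the preset correlation. The adipocyte call ended without array CR715 (median -0.06), and its median was -0.79 and -0.30 without arrays DR716 and DR718. The muscle call ended without arrays CR712, DR716 or DR720 (medians 0.23, 0.39 and 0.08), and its median was 1.10 and 1.13 without arrays CR715 and DR719. Interferon response genes lay higher in 27 of 29, with a median of 0.24 (adjusted p = 2.16e-09, and adjusted p = 0.293 with an estimated correlation). Circadian clock genes lay higher in 13 of 18, with a median of 0.37 (adjusted p = 4.51e-07, 3 genes past the threshold when adjusted over the list alone, and adjusted p = 0.0654 with an estimated correlation). The fatty acid median was -0.19 without array CR715, the cholesterol median -0.43 without array CR715 and -0.12 without array DR716, the interferon median 0.14 without array CR713 or DR716, and the clock median 0.23 without array DR716.

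Macrophage markers were higher in 19 of 21 members, with a median of 0.24 (adjusted p = 4.44e-06, and adjusted p = 0.448 with an estimated correlation), and chemokines and cytokines in 22 of 26, with a median of 0.33 (adjusted p = 7.92e-05, and adjusted p = 0.372 with an estimated correlation). Mast cell markers were higher in 10 of 10, with a median of 0.80 (adjusted p = 1.57e-05, and adjusted p = 0.429 with an estimated correlation). Neutrophil markers were higher in 7 of 7, with a median of 1.67 (adjusted p = 0.00253, and adjusted p = 0.448 with an estimated correlation), a call that ended without array DR719 (median 0.84), whose neutrophil level was 2.11. PPAR gamma targets were lower in 22 of 26, with a median of -0.30 (adjusted p = 7.92e-05, and adjusted p = 0.469 with an estimated correlation). Without array CR715 the PPAR gamma median was -0.05 and the call ended, and it was -0.54 and -0.48 without arrays CR713 and DR716. Without array DR716 the mast cell median was 0.31 and the call ended, and it was 1.21 and 1.24 without arrays CR715 and DR718. The macrophage median was 0.15 without array DR716, and the cytokine median 0.49 without array CR714. In all, 17 lists passed. With limma, 0 of 13460 genes passed an adjusted p of 0.05, and 173 (1.29%) had an unadjusted p under 0.05, 63 higher and 110 lower, with a smallest adjusted p of 1.00. The 3 genes with the smallest p were Pogz, a zinc finger protein, with a difference of -0.42 (SE 0.10), Nudt16l1 with a difference of -0.28 (SE 0.07) and 1 of 2 probe sets of that sign, and BC028528 with 0.55 (SE 0.14). The number at an unadjusted p under 0.05 was 762 without the 5 arrays low in sensory neuron transcripts, 296 without arrays DV706 and DV707, and 356 without array CR715 alone. With array weights it was 999. It was 665 with adipocyte and muscle levels as covariates, 1155 with the sensory neuron level besides, 302 with the sensory neuron level alone and 347 with the Gapdh difference.

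The interaction asked whether rosiglitazone acts differently in diabetic and control mice. The rosiglitazone effect on the chemokine Ccl7 was -1.05 in control mice (n = 4 and 5) and 0.90 in diabetic mice (n = 5 and 5), a difference of 1.95 (SE 0.40). For Lum the effects were -0.54 and 0.58, a difference of 1.12 (SE 0.23). Fibroblast markers had a positive interaction in 17 of 17 members, with a median of 0.30, and macrophage markers in 19 of 21, with a median of 0.49 (adjusted p = 8.68e-05 for both, and adjusted p = 0.610 and 0.759 with an estimated correlation). Endothelial markers had a negative one in 16 of 18, with a median of -0.67 (adjusted p = 8.68e-05, and adjusted p = 0.610 with an estimated correlation). The macrophage median was 0.30 without array DV709, and without the 5 arrays low in sensory neuron transcripts the macrophage and endothelial medians were 0.26 and -0.05 and not past the threshold. In all, 10 lists passed. With limma, 0 of 13460 genes passed an adjusted p of 0.05, and 642 (4.77%) had an unadjusted p under 0.05, 253 positive and 389 negative. With single arrays left out that number ran from 332 without array DV706 to 1847 without array DV710. It was 296 without arrays DV706 and DV707, 317 with the Gapdh difference as covariate and 938 without the 5 arrays low in sensory neuron transcripts. With array weights it was 1290, with adipocyte and muscle levels as covariates 1055, and with the sensory neuron level besides 1441. The adjusted p of Ccl7, Lum and the third gene, C920021L13Rik at -1.15 (SE 0.28), was 0.748. With the mean of the probe sets of a gene, C920021L13Rik was at -0.23.

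The diabetes effects with and without the drug, which share no array, correlated across genes with Pearson's r of 0.235 (jackknife SE 0.685) and Spearman's rho of 0.208. In 100 relabelings of the arrays the 5th to 95th percentiles of r were -0.467 to 0.648. The covariance was 0.0258, against a median of 0.00404 in the relabelings. The rosiglitazone effects with and without diabetes correlated with r of -0.0656 (jackknife SE 0.344; relabelings -0.575 to 0.638) and rho of -0.120, with a covariance of -0.00700 against a median of 0.00912. Neither lay outside the relabelings. Because 0 genes passed in the diabetes comparison, the 200 with the smallest p were followed into the comparison of diabetic mice with and without the drug, and 96% of them had the opposite sign there (jackknife SE 8.85 percentage points). Both comparisons use the diabetic vehicle arrays, and relabelled arrays with the same sharing gave a median of 90.3% and a 95th percentile of 99%. With the diabetic vehicle arrays divided between both comparisons in 10 ways, the mean share was 60.9%, against a median of 45.0% and a 95th percentile of 77.5% in relabelled arrays. Neither share lay above the 95th percentile of the relabelled arrays.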

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

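The tests of sensory and ganglion content, of RNA breakdown in single arrays and of diabetes as the cause of the low sensory levels were chosen only after the result was seen, while the test of RNA breakdown on the number of small p-values, the splits of the arrays and the relabelings were fixed before.

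Arrays DV706, DV707, DV709, CR715 and DR716 were low in transcripts of sensory neuron cell bodies. A further list of ganglion genes, used in place of a first test on the glial gene Fabp7, which had been seen in the pattern, placed 5 of these 5 arrays lowest of the 19, at -1.52 in array CR715, but most of its genes are further sensory neuron genes, so this restates the observation, and whether the other 14 samples may hold ganglion tissue was left open. Its glial genes, named after their values were seen, differed, with Kcnj10 between 6.17 and 8.37 on these arrays and at least 8.85 on the rest, and Ednrb at 9.41 in DV709 but at 11.92 in DV707, 11.83 in DR716 and 11.46 in CR715. Fabp7 itself lay between 4.24 and 6.67 on the 5 low arrays and between 10.30 and 12.31 on the other 14. That goes with ganglion tissue in those 14, but is no independent test, since the gene had been seen in the pattern. RNA breakdown was excluded as the cause for arrays DV709 and CR715, whose highest Gapdh 3' minus 5' difference was 1.24, against up to 1.37 on the 14 arrays, and remained possible for DV706, DV707 and DR716, whose lowest was 1.75. Among the 5 arrays the sensory neuron level did not fall as that difference rose. It was -3.32 in DV709 and -3.07 in CR715, against -3.15 in DR716 (difference 1.75), -2.91 in DV706 (3.71) and -3.17 in DV707 (4.38). This argues against breakdown as the common cause of the low levels, and leaves open its part in arrays DV706, DV707 and DR716. Diabetes was excluded as the whole cause, since 2 diabetic vehicle arrays lay above the highest control vehicle array.

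In the diabetes comparison under vehicle, 2439 genes had an unadjusted p under 0.05. With the sensory neuron level as covariate 13.1% of genes remained, above the limit set for sensory tissue content as the whole cause. The limit was chosen after the result was seen, and a linear covariate may leave part of the tissue differences in place. Sensory tissue content could therefore not be excluded. Whether RNA breakdown may be the cause could not be told, with 5.68% with the Gapdh difference as covariate and 4.50% without arrays DV706 and DV707. Chance could not be excluded, since 9 of 100 splits of the same arrays, the real grouping among them, gave as many genes, the highest other count being 4523. A split that calls many more genes than the real groups points to structure among the samples that the groups do not follow.

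Of the 200 genes with the smallest p for diabetes, 96% had the opposite sign under rosiglitazone. This could come from the diabetic vehicle arrays that both comparisons share, since relabelled arrays reached 99% at their 95th percentile. With those arrays divided between the comparisons the share was 60.9%, against a 95th percentile of 77.5%, so chance could not be excluded there either.

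Chance could be excluded for no count of genes at an unadjusted p under 0.05 and for no count of lists. Each number of splits given here includes the real grouping. For genes past the adjusted threshold the splits are no test, since every split (100 of 100 in each comparison) reaches the real count of 0, and the highest other counts were 1612 for diabetes under vehicle, 3239 for rosiglitazone in diabetic mice, 0 for rosiglitazone in control mice, 0 for diabetes under rosiglitazone and 1539 for the interaction. For genes at an unadjusted p under 0.05, 23 of 100 splits reached the real 1305 for rosiglitazone in diabetic mice (highest 5318), 14 the real 381 in control mice (highest 1025), 67 the real 173 for diabetes under rosiglitazone (highest 2804) and 36 the real 642 for the interaction (highest 4042). For gene lists, 72 splits reached the real 9 for diabetes under vehicle (highest 21), 74 the real 8 for rosiglitazone in diabetic mice (highest 21), 18 the real 19 in control mice (highest 24), 12 the real 17 for diabetes under rosiglitazone (highest 23) and 62 the real 10 for the interaction (highest 22). The real number of lists lay above the median of the splits for rosiglitazone in control mice (median 16) and for diabetes under rosiglitazone (median 12), and at least 12 of 100 splits reached it in every comparison.

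A Dixon test on 70 measures marked 1 array in 36 of 280 groups (12.9%), where chance marks about 1 in 20, with 11 in array DR716, 10 in CR715 and 6 in DV709. Array DR716 stood apart in myelin genes (-0.67), interferon response (0.58), extracellular matrix (0.36), immediate early genes (0.79), circadian clock genes (0.46), the 3' minus 5' differences of Gapdh (1.75) and beta-actin (1.70), and in Pparg (10.63), Cd36 (11.99), Pdk4 (12.72) and Pmp22 (13.95). Array CR715 stood apart in myelin genes (-1.03), oxidative phosphorylation (0.26), ion channels and nodal proteins (-1.63), brown fat markers (1.44), mast cell markers (1.07), non-myelinating Schwann cell markers (-1.39), neuron and axon markers (-3.00), Pmp22 (13.82), Mbp (13.83) and Ngfr (7.85). Array DV709 stood apart in adipocyte markers (-3.55), brown fat markers (-0.70), perineurial markers (0.78), Adipoq (5.48), Fabp4 (9.64) and Myo1h (12.14). Single values stood apart for heat shock genes in CV705 (0.59), B and plasma cell markers in CR714 (1.45), Mbp in DV706 (14.44), Dbp in DV710 (11.97), Mier2 in CV703 (9.61), Stxbp3 and Nudt16l1 in CR711 (10.47 and 12.33), and Myo1h and BC028528 in DR719 (11.80 and 11.32).

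In 10 lists both rosiglitazone effects differed by camera at the preset correlation, and in none with an estimated one. The medians of the difference were -0.67 for endothelial markers, 0.30 for fibroblast markers, 0.49 for macrophage markers, 0.15 for extracellular matrix, 0.53 for cytokines and chemokines, 1.54 for neuron and axon markers, 0.19 for antioxidant genes, 0.16 for heat shock and unfolded protein response, -0.27 for fatty acid and triglyceride synthesis and 2.22 for neutrophil markers. Array CV703, which enters the neutrophil value, held a neutrophil level of 3.13, against -1.43 to 0.93 in the other control vehicle arrays.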

How the results depend on the processing

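The settings with the sensory neuron level as covariate, with 3 tissue levels as covariates, and without the 5 arrays low in sensory neuron transcripts or the 2 with the highest 3' minus 5' differences were chosen only after the result was seen. Ces1f, Poc5 and Srpx lie outside the rule for named genes and were named after their values were seen. The cause was not tested for any changed result below, except where the removal of arrays itself makes the change. With adipocyte and muscle covariates 1 gene passed for diabetes under vehicle, Ces1f at 2.13, and the correlation of the rosiglitazone effects was 0.306. With array weights 20 genes passed for rosiglitazone in control mice. With an estimated correlation camera called 0 lists for diabetes under vehicle, 0 for rosiglitazone in diabetic mice, 0 in control mice, 1 for diabetes under rosiglitazone and 0 for the interaction, and fry called 0 in each of the 5 comparisons. Without a filter, 13 lists passed for rosiglitazone in diabetic mice. The sensory neuron covariate gave 13 there and a correlation of 0.102 between the rosiglitazone effects. With all 3 tissue covariates 1 gene passed for diabetes under vehicle, with 5 lists, 1 list passed for rosiglitazone in diabetic mice, and the correlation of the rosiglitazone effects was 0.0375. Without the 5 low arrays, which carry the difference in neuron content, neuron and axon markers reversed, to 0.76 for diabetes under vehicle, -0.30 for rosiglitazone in diabetic mice and -0.75 for the interaction. Those arrays were chosen by sensory neuron markers that share genes with this list, so its reversal follows in part from the choice. In the same setting 4 lists passed for rosiglitazone in diabetic mice, and the correlation of the diabetes effects was -0.00261. Without arrays DV706 and DV707 the rosiglitazone correlation was 0.202 and the share of opposite signs 86%. Leaving out each array in turn gave 0 to 4 genes for diabetes under vehicle (4 without DV710, Ccl7, Poc5, Pole4 and Srpx), 3 to 12 lists for rosiglitazone in diabetic mice (without DV709 and DV706), a correlation of the diabetes effects of -0.300 to 0.448 and of the rosiglitazone effects of -0.166 to 0.150 (without DR716 and CR715 in both), and a share of 91.5% to 98.5%. Of list changes under settings fixed beforehand, 2650 kept their result, called or not, 142 gained a call and 248 lost one.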

Other observations

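The sensory neuron and oligodendrocyte lists below, and the glial genes named with them, were chosen only after the result was seen.

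Genes known from glia of the central nervous system also spanned wide ranges. Aqp4, a water channel of astrocytes, ran from 3.23 to 12.72 across arrays, and Mobp, a myelin gene of oligodendrocytes, from 4.05 to 12.25. The oligodendrocyte level was -0.97 in array CV703 and -1.40 in array DR720, where the sensory neuron level was 1.02 and 1.53. It was also low, between -1.33 and -0.67, on the 5 arrays low in sensory neuron transcripts. Fabp7, a gene of satellite and radial glia, ran from 4.24 to 12.31.

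Injury and repair genes of Schwann cells, which are induced after nerve damage, were lower with diabetes under vehicle in 16 of 19 members, with a median of -0.41, and did not pass the threshold (adjusted p = 0.734 with an estimated correlation, and over 0.05 at the preset one). The level of that list was -0.21, -0.61 and -0.35 in arrays DV706, DV707 and DV709 and 0.19 and 0.18 in arrays DV708 and DV710, against 0.19 to 0.22 in control vehicle mice. Arrays DV706 and DV707 had the highest Gapdh 3' minus 5' differences. Arrays DV706, DV707 and DV709 are also among the 5 arrays low in sensory neuron transcripts. Of those 5, CR715 and DR716 had levels of -0.46 and -0.26. Arrays CR711 and DR720, which were not low in sensory neuron transcripts, were at -0.23 and -0.47.

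The first principal component of the arrays held 48.4% of the variance and the second 12.4%. The median correlation of an array with the others was 0.876, 0.862, 0.898, 0.888 and 0.890 for arrays DV706, DV707, DV709, CR715 and DR716, and at least 0.953 for the rest. The lowest array weight was 0.195, in array DV707.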
